A study of Mus musculus with 6 samples.

How the data were processed

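RNA of sorted glomerular endothelial cells from eNOS-null mice without treatment (control, 3 libraries) and with STZ (3 libraries) was analysed from 1 table per library. Per the labels, RNA of 4 mice was pooled per sample, about 200000 cells were sorted per mouse and RNA integrity values were above 7.5. Groups and replicate numbers were taken from the labels. The numbers do not pair control with STZ libraries, so no pairing entered the tests, and a replicate block was an alternative. The deposited files hold 1 count value per gene, treated here as an expected count, with RefSeq accession, coordinates and transcript length. The genome build mm10 and limma are named in the submitters' processing notes. The aligner, the counting tool, the strand setting and the filter on genes are not given in the sources used here.

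Each file listed the same 12911 genes. Every value was a multiple of 0.5, and 2251 genes had a fractional value in at least 1 library. Such values occurred in 0 of 9340 genes with 1 listed transcript, in 90.1% of 2443 genes with an even number and in 4.4% of 1128 genes with a larger odd number, a pattern near that of a median over transcript counts, although a median of whole counts would give none in the last group. How genes with several transcripts were summarised is not given in the labels or files. The 34 blank cells, in 30 genes, were read as 0, since no cell held a 0. There were 19 symbols that look like dates, and 1 symbol occurred more than once. No gene of the mitochondrial chromosome was listed. The listed starts plus 1 equalled a GENCODE transcript start in 2999 of 5519 genes whose end matched one, against 298 for the starts as listed, so 1 was added to give 1-based coordinates in mm10.

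Values were rounded to whole counts. Genes were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr with default settings, TMM normalization, robust quasi-likelihood fit and F test, two-sided), with Benjamini-Hochberg adjustment over the 12786 tested genes and a threshold of 0.05. CPM are counts scaled to the TMM-normalised library size (cpm of edgeR), and errors are SD over the 3 libraries of a group or SE of the fitted log2 fold change. Biological coefficient of variation was 0.117. A set of 30 gene lists, of processes and of markers of the cell types that the sort could hold, was tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01, lists with at least 5 tested members, Benjamini-Hochberg over the 28 lists that had them). The mitochondrially encoded and lymphatic lists had too few members to test. Camera with an estimated correlation and fry were run beside it. With an estimated correlation 0 of 28 lists passed, the smallest adjusted p being 0.156, and 4 lists had an unadjusted p under 0.05, whereas fry called 10. The lists held 724 tested genes, 33 of them in more than 1 list.

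The test, the thresholds, the lists, the rule for named genes and most of the alternative settings were fixed before the data were examined. Named genes were Nos3, Lrg1, Kdr, Flt1, Pecam1, Cdh5, Ehd3, Emcn and Txnip, then the 10 higher and 10 lower called genes with the smallest p whose libraries did not overlap between groups, then the 10 called genes with the largest absolute log2 fold change and a mean log2 CPM of at least 3. Up to 4 called members of each list with the smallest p (or, without calls, 2 as values) and the 2 most abundant members of each marker list were added. Symbols of predicted genes and pseudogenes were left out. Some genes that the rule took are not reported here. The other 117, of which 99 were called, are the named genes, and only part of them is printed. Any other gene is said where it is named to have been chosen after its values were seen.

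The pipeline was tested on simulated data of the same depth and spread, in which 12758 simulated genes were tested. Changes were added to 67 genes at 1.5-fold, 67 at 2-fold and 66 at 4-fold, far fewer than the 1251 genes called in the real data. The pipeline recovered 59.7% of the genes changed 1.5-fold, 83.6% of those changed 2-fold and 100% of those changed 4-fold. Of its calls 10.5% were unchanged genes, more than the threshold is meant to allow. Of true values 96.5% lay within the 95% interval. The list test called the shifted list and 0 of the others. Simulated genes were drawn independently of each other, whereas the estimated correlation between members reached 0.924 in the podocyte list. The simulation therefore does not test the preset correlation for lists whose members move together. Total counts of 4387339 to 12662371.5 per library set this precision, which covers counting error and the spread between pools.

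The alternative settings fixed at that time were the DESeq2 size factors and upper-quartile normalization, no filter and a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom with and without sample weights, a fit that was not robust, a threshold of 0.10, an absolute log2 fold change of at least 1, a replicate block and leaving out each library in turn. Alternatives added after the data were seen were libraries thinned to the shallowest, removal of trends with GC content and length (GC known for 99.6% of genes), and leaving out genes with a blank cell, with more than 1 listed transcript or on X and Y. The mean of podocyte or of mesangial and mural markers as a covariate was added as well. Enrichment of annotation terms carried in the files (2045 terms of 10 to 300 genes, hypergeometric test, Benjamini-Hochberg) was also chosen after the data were seen. Allele, isoform and read-level checks were left out because the files hold values per gene.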

Results

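RNA sequencing was carried out on glomerular endothelial cells, the fenestrated capillary cells of the kidney's filtering unit, from mice lacking endothelial nitric oxide synthase (eNOS-null). The animals had or had not received streptozotocin (STZ), a toxin of pancreatic beta cells that is used to induce diabetes. Glomeruli were collected with magnetic beads and digested, and the endothelial cells were sorted by EYFP fluorescence. There were 3 control and 3 STZ libraries, each holding pooled RNA of 4 mice, so errors and p-values measure the spread between pools and not between single mice. Total deposited counts were 8751732.5, 6020083 and 4387339 in control pools 1, 2 and 3. They were 10734376, 12069443 and 12662371.5 in STZ pools 1, 2 and 3, so every STZ library was deeper than every control library. The question that the labels set is which genes differ between glomerular endothelial cells of eNOS-null mice with and without STZ.

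Nos3, which encodes eNOS and is the gene the genotype targets (NM_008713; mm10 chromosome 5, 24364819 to 24384474, plus strand), had deposited counts of 7711, 4711 and 4152 in the control pools and of 6339, 8657 and 8243 in the STZ pools. In CPM (counts scaled to library size) this was 840 ± 80.5 (SD, n = 3) in control and 676 ± 68.3 (SD, n = 3) in STZ. The log2 fold change of STZ over control was -0.31 ± 0.11 (SE), with an adjusted p of 0.091 by the edgeR quasi-likelihood test, so Nos3 did not pass the threshold there. It was called lower by limma-voom with sample weights (adjusted p = 0.0410), after removal of GC and length trends (0.0396) and with the podocyte covariate (0.00552), and not by DESeq2 or by limma-voom without weights. A count per gene does not show whether the transcripts carry the null allele, and the genotype rests on the labels.

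In STZ pools Fkbp5, Zbtb16 and Lrg1 rose, while Calca and Vegfc fell. Fkbp5, a co-chaperone of the glucocorticoid receptor (NM_010220; mm10 chromosome 17, 28398753 to 28486149, minus strand), rose from 26.6 to 233 CPM, a log2 fold change of 3.12 ± 0.09 (SE, n = 3 against 3; adjusted p = 1.46e-10 by edgeR quasi-likelihood). Zbtb16, a transcription factor that is also induced by glucocorticoids, rose by 3.53 ± 0.21 on the log2 scale. Lrg1, a secreted glycoprotein that acts on TGF-beta signalling in endothelial cells (NM_029796; mm10 chromosome 17, 56119678 to 56121946, minus strand), rose from 5.98 ± 1.81 to 43.3 ± 11.1 CPM (SD, n = 3 each), a 7.31-fold difference (adjusted p = 8.52e-05). Calca, which encodes calcitonin and the vasodilator peptide CGRP, fell from 199 to 68.1 CPM (log2 fold change -1.55 ± 0.11, adjusted p = 2.34e-06). Vegfc, a growth factor of lymphatic and blood vessels, fell from 44.9 to 17.8 CPM (-1.33 ± 0.12, adjusted p = 1.88e-05).

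Other genes that rose with small p-values were Cdc42ep4, a Cdc42 effector (1.66 ± 0.09), Ucp2, a mitochondrial carrier (1.65 ± 0.09, from 319 to 999.7 CPM), Fam213a, a peroxiredoxin-like protein (1.98 ± 0.12), and Fkbp14, a prolyl isomerase of the endoplasmic reticulum (1.53 ± 0.10). Cttnbp2, a cortactin-binding protein (-1.13 ± 0.10), Atp2b2, a plasma membrane calcium pump (-1.20 ± 0.13), Nrep (-1.06 ± 0.11), Pitpnm3 (72.4 to 35.9 CPM) and Ssu2 (-0.84 ± 0.10) fell. Values other than CPM are log2 fold changes with their SE, and adjusted p ran from 1.79e-07 for Cdc42ep4 to 0.000185 for Pitpnm3.

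**Figure D1:**
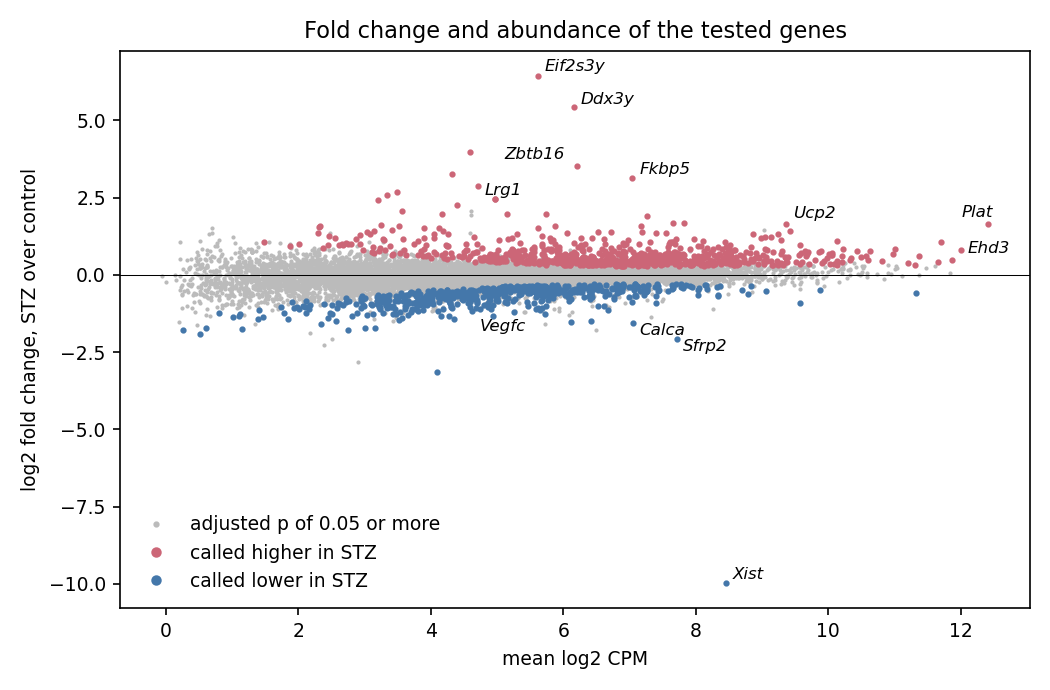
Log2 fold change of STZ over control (vertical axis) against mean log2 CPM (horizontal axis), 1 point per tested gene, with the 699 genes called higher in STZ in red and the 552 called lower in blue. Xist lies lowest at -9.96 and Eif2s3y highest at 6.43.

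The libraries also split completely by sex-linked genes along the same line as the treatment, and the labels give no sex. Xist, the RNA that silences the second X chromosome in female cells (mm10 chromosome X, 103460373 to 103483233, minus strand), had rounded counts of 6276, 4299 and 3378 in control pools against 4, 10 and 10 in STZ pools. This was 709 ± 32.4 against 0.687 ± 0.261 CPM (SD, n = 3 each; adjusted p = 4.39e-13). The Y-linked genes went the other way. Ddx3y had counts of 29, 21 and 12 in control pools against 1353, 1564 and 1717 in STZ pools (log2 fold change 5.43 ± 0.15), and Eif2s3y rose by 6.43 ± 0.25, Kdm5d by 3.99 ± 0.20 and Uty by 3.25 ± 0.20. All 5 tested genes of the list of sex-linked genes were called, 4 higher and 1 lower, and 4 and 1 when adjusted over the list alone. The list median was 3.99 (adjusted p = 3.97e-05, and adjusted p = 0.156 with an estimated correlation). Every difference between STZ and control given here is therefore also a difference between pools with high and with almost no Xist.

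**Figure D2:**
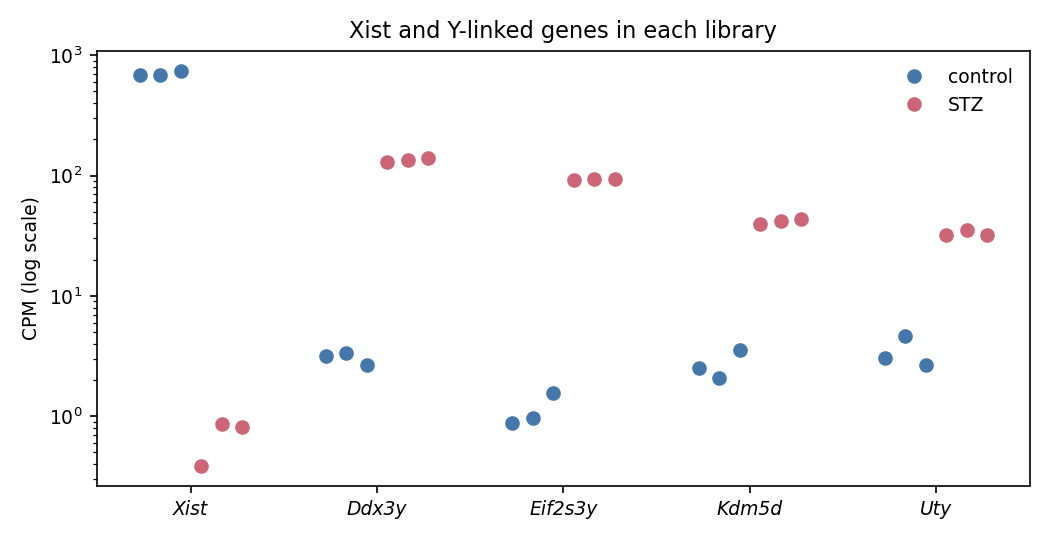
CPM on a log axis of Xist and the Y-linked genes in each of the 6 libraries, 1 point per library, control in blue and STZ in red. All 3 control libraries had Xist and all 3 STZ libraries had Ddx3y, Eif2s3y, Kdm5d and Uty at high levels.

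Of 12786 tested genes, 1251 (9.78%) passed an adjusted p of 0.05 in the edgeR quasi-likelihood test, 699 higher and 552 lower in STZ, with a median absolute log2 fold change of 0.59. A log2 fold change of at least 1 was reached by 98 of the higher and 92 of the lower genes. The 3 libraries of a group lay wholly above or below those of the other in 1247 of the called genes and in 29.1% of the tested genes, where chance gives 10%. Called genes were as frequent on the X chromosome (40 of 414, 9.66%) as on autosomes and unplaced sequences (9.77%), and 4 of 10 tested Y-linked genes were called. The first principal component held 46.3% of the variance and separated the groups, with control pools at -19.0, -22.9 and -21.2 and STZ pools at 20.4, 26.03 and 16.6. A second component with 24.4% split pools within the groups. Control pools lay at 8.37, 16.6 and -27.8 on it and STZ pools at 7.76, -13.3 and 8.35. Without control pool 1 the count of called genes was 720 and without STZ pool 1 it was 662, and without STZ pool 3 the count of lower genes was 355.

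Of 26 tested glomerular endothelial identity genes, 11 were called higher, 2 lower and 13 did not pass. Adjusted over the list alone, 14 were higher and 3 lower. The median log2 fold change was 0.27 (adjusted p = 8.69e-05 over the 28 lists, and adjusted p = 0.186 with an estimated correlation). Plat, the tissue plasminogen activator, rose from 2631 to 8303 CPM (1.66 ± 0.14). Ehd3, a membrane-trafficking protein enriched in glomerular endothelium, rose from 3001 to 5230.0 CPM (0.80 ± 0.11). Kdr, the main VEGF receptor, rose from 1208 to 1843 CPM (0.61 ± 0.10, adjusted p = 0.00137), and the junction protein gene Esam by 0.58 ± 0.09. The vascular cadherin gene Cdh5 rose by 0.47 ± 0.10. The sialomucin gene Emcn rose by 0.42 ± 0.11 (adjusted p = 0.0355), a call lost without control pool 1 (adjusted p = 0.0612), STZ pool 1 (0.182) or STZ pool 3 (0.0995). The Emcn call was also lost with a replicate block (adjusted p = 0.0635) or a fit that was not robust (0.0512). Pecam1 (0.30 ± 0.09, adjusted p = 0.060) and Flt1 (0.25 ± 0.09, adjusted p = 0.130) did not pass in edgeR with all 6 libraries but did without control pool 3 (adjusted p = 0.0479 and 0.0333) and after removal of GC and length trends (0.0355 and 0.0372). DESeq2 (adjusted p = 0.0124) and limma-voom (0.0491) called Pecam1 with all 6. Members did not move together: Plvap, the diaphragm protein of other fenestrated endothelia, fell (-0.69 ± 0.12), and the angiopoietin receptor genes Tek (0.02) and Tie1 (-0.01), chosen after their values were seen, were near 0.

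Of 32 genes of TGF-beta and BMP signalling, 13 were called higher, 3 lower and 16 did not pass, and 18 were higher and 3 lower when adjusted over the list alone. Their median was 0.31 (adjusted p = 3.74e-05, and adjusted p = 0.297 with an estimated correlation). Besides Lrg1, the decoy receptor gene Bambi (1.25 ± 0.10) and Skil, a repressor of SMAD proteins (0.85 ± 0.12), rose. The members that fell, chosen after their values were seen, were Smad3 (-0.63 ± 0.09), which carries the TGF-beta signal to the nucleus, and the ligand genes Tgfb2 (-1.52 ± 0.19) and Bmp2 (-0.69 ± 0.16). Coagulation and fibrinolysis genes rose in 7 of 17 members, including Plat, the scavenger receptor gene Cd36 (1.20 ± 0.13) and the protein S gene Pros1 (0.58 ± 0.09). The tissue factor gene F3, chosen after its value was seen, was the only member called lower by edgeR (-0.99 ± 0.28), whereas DESeq2 called 3 members lower and limma-voom 0. The F3 call was also lost with a replicate block (adjusted p = 0.0629), with a fit that was not robust (0.0538), and without control pools 1 or 2 (0.136 and 0.142) or STZ pools 2 or 3 (0.106 and 0.112). Thinned, F3 stood at -0.77 (adjusted p = 0.176), with the podocyte covariate at -0.53 (0.261) and with the mesangial and mural covariate at -0.41 (0.766). Adjusted over the list alone, 8 coagulation genes were higher and 2 lower. The coagulation median was 0.21 (adjusted p = 0.00282, and adjusted p = 0.186 with an estimated correlation).

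The angiogenesis and vascular growth list was not called (adjusted p = 0.552), although 9 of its 36 members were called higher and 3 lower, and 9 and 5 when adjusted over the list alone. Its median was -0.02, whereas its mean was 0.04 and its test pointed upward. Without 1 library the angiogenesis median ran from -0.0432 (control pool 1) to 0.0069 (control pool 2). Kdr, Lrg1 and the protease gene Adamts1 (0.68 ± 0.10) rose while Vegfc fell. Nitric oxide and vasoactive genes likewise went both ways, with 7 of 27 called higher and 2 lower, and 7 and 7 when adjusted over the list alone (median 0.03, mean -0.01, test upward, adjusted p = 0.488 by camera). The vasoactive list was called higher by fry (adjusted p = 0.0185), and its median ran from -0.0667 without STZ pool 2 to 0.1297 without control pool 2. Adm, the vasodilator adrenomedullin (1.01 ± 0.12), its receptor component Ramp2 (0.65 ± 0.10), the angiotensin-converting enzyme gene Ace (0.89 ± 0.12) and the inducible synthase gene Nos2 (0.82 ± 0.12) rose. Gucy1b3, a subunit of the nitric oxide receptor (-1.04 ± 0.22), and the endothelin receptor gene Ednra (-0.73 ± 0.20), both expressed by mural cells and chosen after their values were seen, fell. Gucy1b3 lost its call without control pools 1 or 2 (adjusted p = 0.0766 and 0.0711), and Ednra without every library but STZ pool 3 (adjusted p of 0.0515 to 0.099).

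Markers of other endothelial beds moved in both directions and neither list was called by camera. Of 19 arterial and arteriolar markers, 3 were called higher and 4 lower, and 3 and 5 when adjusted over the list alone (median -0.07, adjusted p = 0.276). The arterial median ran from -0.1021 without STZ pool 1 to -0.0206 without STZ pool 2. The connexin gene Gja4 (1.06 ± 0.09) was higher and Vegfc, the chemokine gene Cxcl12 (-1.07 ± 0.18) and the matrix gene Fbln2 (-0.51 ± 0.09) were lower. Of 13 peritubular and venous markers, 3 were called higher and 2 lower, and 5 and 3 when adjusted over the list alone (median 0.04, adjusted p = 0.336). That list was called higher by fry (adjusted p = 0.0383), which does not compare a list with other genes. The peritubular median ran from -0.0349 without STZ pool 3 to 0.204 without control pool 1. Cd36, the ephrin receptor gene Ephb4 (0.54 ± 0.09) and the water channel gene Aqp1 (0.71 ± 0.12) were higher and Plvap and Igfbp5 (-0.60 ± 0.12) lower. The lymphatic list had 3 tested members and was not tested as a list.

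Of 24 members of the unfolded protein response, 11 were called higher and the other 13 did not pass, and 16 were higher when adjusted over the list alone. Their median was 0.28 (adjusted p = 7.60e-08, and adjusted p = 0.156 with an estimated correlation). Hspa5, the main chaperone of the endoplasmic reticulum (0.80 ± 0.10, from 279 to 488 CPM), the calcium-binding chaperone gene Calr (0.73 ± 0.10), Hsp90b1 (0.69 ± 0.10) and the disulfide isomerase gene Pdia6 (0.54 ± 0.09) were among them. Immediate early and dissociation stress genes had 12 of 29 members called higher and the other 17 not past the test, and 14 higher and 3 lower when adjusted over the list alone. The stress list had a median of 0.33 (adjusted p = 0.00121, and adjusted p = 0.522 with an estimated correlation). Without STZ pool 2 that median was 0.163, and fry did not call the list (adjusted p = 0.0884). Those called higher included the cytokine signalling inhibitor Socs3 (1.56 ± 0.18), the small GTPase gene Rhob (0.84 ± 0.13), Btg2 (0.74 ± 0.09) and the phosphatase gene Dusp1 (0.53 ± 0.10). In the p53 and apoptosis list, 8 of 25 members were called higher and 2 lower, and 12 and 4 when adjusted over the list alone. The p53 list had a median of 0.26 (adjusted p = 0.00195, and adjusted p = 0.339 with an estimated correlation). The cell cycle inhibitor Cdkn1a (1.68 ± 0.13), the survival gene Bcl2l1 (1.32 ± 0.09), the death receptor gene Fas (0.74 ± 0.10) and Sesn1 (0.59 ± 0.10) rose, and the kinase gene Plk2, chosen after its value was seen, fell (-0.36 ± 0.10). Plk2 lost its call with a replicate block (adjusted p = 0.0825) and without control pool 1 (0.1396), STZ pool 1 (0.167) or STZ pool 3 (0.144).

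Smaller shifts upward were measured in the cell cycle list, where 3 of 26 members were called higher and 5 when adjusted over the list alone. The cell cycle median was 0.23 (adjusted p = 0.00121, and adjusted p = 0.321 with an estimated correlation), and the replication helicase gene Mcm3 rose by 0.47 ± 0.10. The called member Top2a (0.73 ± 0.17) lost its call without control pool 2 (adjusted p = 0.0584) or STZ pool 3 (0.0794). Ccnd1 (0.35 ± 0.09) lost its call without every library but control pool 3 (adjusted p of 0.0503 to 0.1615) and with a replicate block (0.0790). Glycolysis and glucose handling genes had 4 of 30 called higher, and 12 higher and 4 lower when adjusted over the list alone. The glycolysis median was 0.08 (adjusted p = 0.0358, and adjusted p = 0.733 with an estimated correlation). The glucose-responsive gene Txnip, a thioredoxin inhibitor, rose from 1175 to 1984 CPM (0.76 ± 0.10, adjusted p = 0.000403). Mlxip, a glucose-sensing transcription factor (1.00 ± 0.13), Pfkfb3 (0.83 ± 0.11) and Gapdh (0.46 ± 0.09), both of glycolysis, rose too. The glycolysis call was lost without control pool 3 (adjusted p = 0.455), STZ pool 1 (0.0604) or STZ pool 3 (0.0948), and the median ran from 0.0186 without control pool 3 to 0.237 without control pool 2. Nuclear genes of oxidative phosphorylation had a median of 0.09, with 1 of 74 called, Ndufc2 (0.47 ± 0.12). That call was lost without control pool 1 (adjusted p = 0.109), control pool 3 (0.0531), STZ pool 1 (0.121) or STZ pool 2 (0.0658). Adjusted over the list alone none passed, while 4 had an unadjusted p under 0.05 in edgeR and DESeq2 and limma-voom each called 1. This list (adjusted p = 0.0255, and adjusted p = 0.838 with an estimated correlation) was not called without control pool 1 (adjusted p = 0.0523), control pool 3 (0.821) or STZ pool 1 (0.380), and its median ran from 0.0072 without control pool 3 to 0.179 without control pool 2. Oxidative stress defence genes had 2 of 28 called higher and 6 when adjusted over the list alone. Their median was 0.11 (adjusted p = 0.0413, and adjusted p = 0.726 with an estimated correlation), and the call was lost without control pool 1 (adjusted p = 0.0765), control pool 3 (0.379), STZ pool 1 (0.190) or STZ pool 3 (0.0708). Without control pool 2 the median was 0.212. The mitochondrially encoded genes had no listed member and were not tested.

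Lipid and sterol genes went both ways and the list was not called (adjusted p = 0.751, median -0.00, mean 0.11, test upward): 5 of 35 were called higher and 6 lower, and 8 and 8 when adjusted over the list alone. The lipid median ran from -0.029 without STZ pool 1 to 0.0749 without STZ pool 3. Among those that rose were Gpihbp1, which anchors lipoprotein lipase to capillaries (1.39 ± 0.11), Lpl (1.42 ± 0.22), Fabp4 (1.09 ± 0.11, from 716 to 1522 CPM) and the fatty acid transporter gene Cd36. Among those that fell were the sterol synthesis gene Sqle (-0.50 ± 0.12), Insig1 (-0.46 ± 0.09) and Srebf2, a regulator of sterol synthesis (-0.40 ± 0.10). Lpl, Sqle, Insig1 and Srebf2 were chosen after their values were seen. Lpl lost its call without STZ pool 1 (adjusted p = 0.0505), and Sqle without control pool 2 (0.0583) or STZ pool 1 (0.0749). Srebf2 lost its call without control pools 2 or 3 (adjusted p = 0.0631 and 0.069) or STZ pools 1 or 3 (0.121 and 0.0832).

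Leukocyte adhesion and inflammatory mediators had 5 of 25 members called higher and 3 lower, and 7 and 4 when adjusted over the list alone. The median was 0.15 (adjusted p = 0.0413, and adjusted p = 0.636 with an estimated correlation). The adhesion molecule genes Icam1 (0.84 ± 0.10) and Sele (1.46 ± 0.21), the chemokine gene Cxcl16 (1.32 ± 0.12) and the NF-kappaB inhibitor Nfkbia (0.69 ± 0.09) rose. Cxcl12 and the NF-kappaB subunit genes Relb (-0.69 ± 0.12) and Nfkb2 (-0.71 ± 0.12), the subunits chosen after their values were seen, fell. The list was not called without control pool 3 (adjusted p = 0.0859), STZ pool 1 (0.0604), STZ pool 2 (0.0760) or STZ pool 3 (0.0579). Nor was it called with a replicate block (adjusted p = 0.053) or by fry (0.0884). The interferon list was not called (adjusted p = 0.748, median -0.01, mean 0.02, test upward), with 4 of 33 members higher, and 4 when adjusted over the list alone. The direction of its test reversed without control pool 2 (median -0.0021) and without control pool 3 (-0.0228). Its 4 called members, Bst2 (0.45 ± 0.10), Ifitm3, Irf7 and Isg15, all lost the call without STZ pool 1 (adjusted p = 0.0636, 0.147, 0.152 and 0.2365). Apart from the fold minimum, they lost it in 1, 5, 7 and 9 of the settings fixed in advance, in that order. Antigen presentation genes (median 0.04, adjusted p = 0.371) had 2 of 20 called higher, and 3 when adjusted over the list alone. The antigen presentation median ran from -0.0112 without control pool 3 to 0.0616 without STZ pool 3. B2m, the light chain of class I molecules, rose by 0.61 ± 0.12, and the heavy chain gene H2-D1 by 0.47 ± 0.10, a call lost without control pool 1 (adjusted p = 0.0533) or STZ pool 1 (0.0618).

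Glycocalyx and heparan sulfate genes were not called as a list (median -0.08, adjusted p = 0.673), with 4 of 27 members higher and 3 lower, and 5 and 3 when adjusted over the list alone. The direction of that test reversed without control pool 2 (median -0.11). The proteoglycan gene Sdc3 (0.65 ± 0.10) and the hyaluronidase gene Hyal2 (0.56 ± 0.09) rose, and Xylt1, which starts glycosaminoglycan chains, fell (-1.44 ± 0.29). Basement membrane and extracellular matrix genes (median -0.12, adjusted p = 0.371) had 2 of 40 members higher and 3 lower, and 2 and 4 when adjusted over the list alone. The basement membrane collagen gene Col18a1 rose by 0.56 ± 0.09, and the microfibril gene Fbn1 (-0.59 ± 0.13) fell, a call lost without STZ pool 1 (adjusted p = 0.0565). The other member that rose, the protease inhibitor gene Timp3 (0.49 ± 0.10), lost its call without STZ pool 1 (adjusted p = 0.0557) or STZ pool 3 (0.0552). The collagen gene Col6a3 (-0.91 ± 0.19) fell, a call lost without control pool 1 (adjusted p = 0.0619). The matrix median ran from -0.2019 without STZ pool 3 to -0.0511 without control pool 1. Ribosomal protein genes had a median of 0.05 (adjusted p = 0.175). None of 81 members was called by edgeR, also when adjusted over the list alone, while 4 had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0. That list was called without control pool 2 (median 0.13, adjusted p = 0.000641) or STZ pool 2 (0.11, adjusted p = 0.00711), and its direction reversed without control pool 3 (-0.05) and without STZ pool 1 (-0.04).

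**Figure D3:**
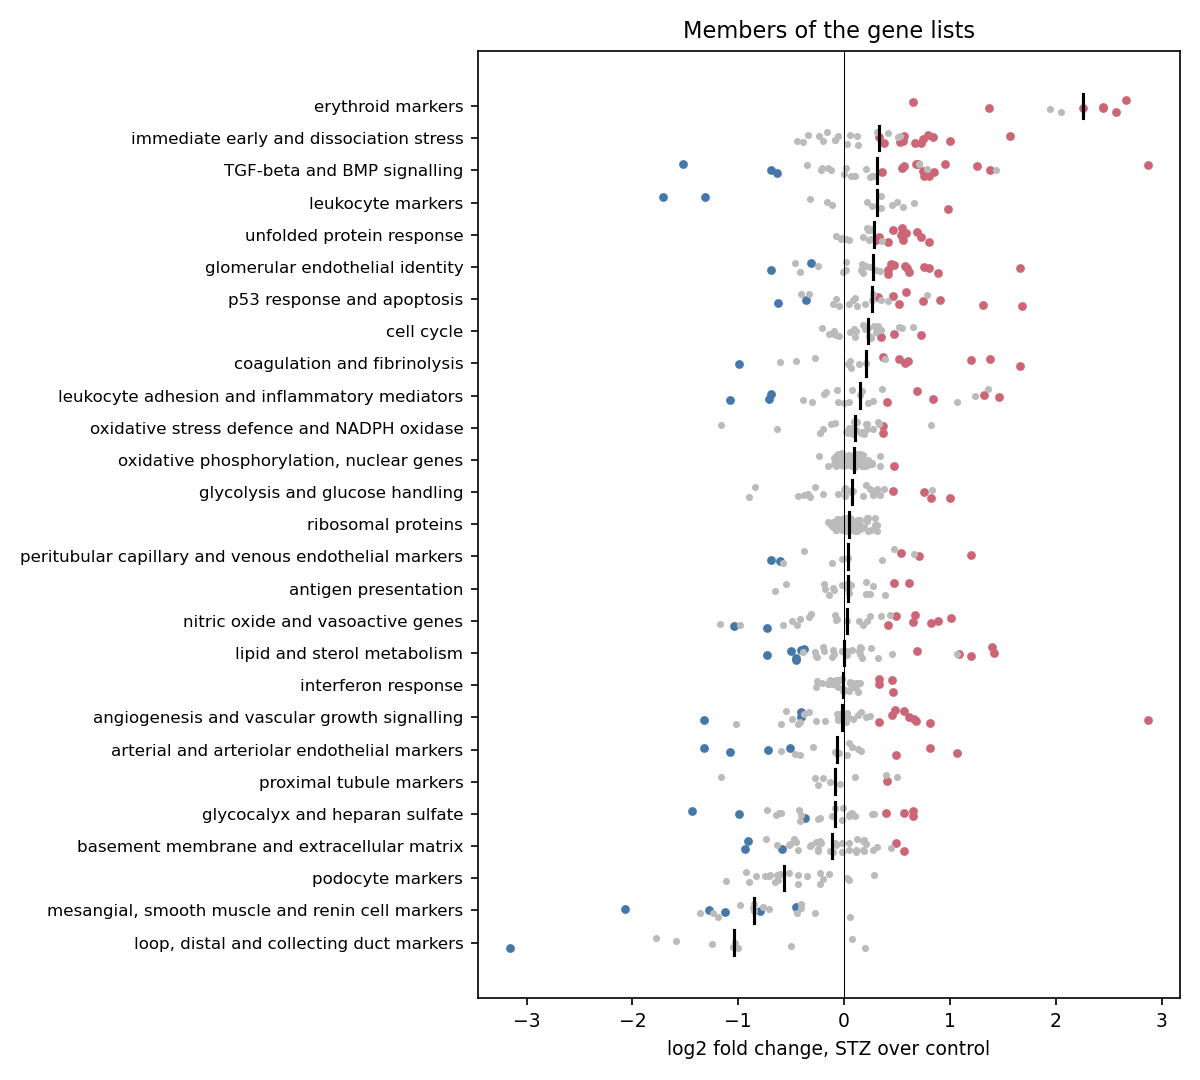
Log2 fold change of STZ over control (horizontal axis) of every tested member of the tested gene lists other than the sex-linked genes, 1 point per gene, red if called higher, blue if called lower and grey if not called, with a black bar at each list's median. The erythroid markers had a median of 2.25, and the mesangial and mural markers of -0.85.

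Several marker lists of other cells were called by camera beside these endothelial gene groups. In the podocyte and loop lists the pools of the groups overlapped. Of 19 mesangial, smooth muscle and renin cell markers, 5 were called lower and 14 did not pass. Adjusted over the list alone 10 were lower, and 18 had a negative fold change. Their median was -0.85 (adjusted p = 1.42e-08, and adjusted p = 0.479 with an estimated correlation), and fry did not call the list (adjusted p = 0.0777). Their mean log2 CPM was 6.91, 6.97 and 6.80 in control pools and 6.17, 5.47 and 6.36 in STZ pools. The pericyte genes Rgs5 (-1.13 ± 0.12, from 69.2 to 31.7 CPM) and Cspg4 (-1.28 ± 0.16) fell, and so did the smooth muscle myosin gene Myh11 (-0.79 ± 0.17), a call lost without control pool 1 (adjusted p = 0.0642), control pool 2 (0.0704) or STZ pool 1 (0.0886). Sfrp2, a secreted Wnt modulator, fell from 340.0 to 81.2 CPM (-2.07 ± 0.36, adjusted p = 0.0355), a call lost without control pools 1, 2 or 3 (adjusted p = 0.0720, 0.0877 and 0.0978), STZ pool 1 (0.115) or STZ pool 3 (0.0736). The Sfrp2 call was also lost with a replicate block (adjusted p = 0.179). The most abundant of these markers, Cald1 (380 to 287 CPM, -0.41 ± 0.12) and Mylk (413 to 341 CPM, -0.28 ± 0.13), did not pass in edgeR (adjusted p = 0.0538 and 0.196). Cald1 was called by DESeq2 (adjusted p = 0.0202), with upper-quartile normalization (0.0485), thinned (0.0404) and after removal of GC and length trends (0.0417).

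Podocyte markers had a median of -0.56 (adjusted p = 0.0126, and adjusted p = 0.773 with an estimated correlation). None of 22 members was called by edgeR, also when adjusted over the list alone, while 1 higher and 3 lower had an unadjusted p under 0.05, DESeq2 called 1 lower and limma-voom 0. Their mean log2 CPM varied within control (7.59, 7.77 and 6.70) as much as between the groups (7.05, 6.72 and 7.10 in STZ). The podocyte list was not called without control pool 1 (adjusted p = 0.112), control pool 2 (0.264, median -0.37) or STZ pool 2 (0.146). Podxl, the most abundant of them, which endothelial cells also make, had 3581 CPM in control and 3708 CPM in STZ. Loop, distal and collecting duct markers had a median of -1.04 (adjusted p = 0.0227, and adjusted p = 0.726 with an estimated correlation). Of 10 members 1 was called lower, also when adjusted over the list alone. That list was not called without control pool 2 (adjusted p = 0.109, median -0.49) or STZ pool 2 (0.149, median -0.52), and its median was -1.84 without STZ pool 3. The mean log2 CPM of the loop list was 4.74, 5.66 and 3.88 in control pools and 4.05, 2.12 and 4.397 in STZ pools. It was lowest in STZ pool 2, and control pool 3 lay below STZ pools 1 and 3. The called member Slc12a1 (-3.16 ± 0.65) stood at an adjusted p of 0.0497 and was lost without control pool 3 (0.0829) or STZ pools 1, 2 or 3 (0.190, 0.164 and 0.177). Slc12a1 was also lost with DESeq2 size factors (adjusted p = 0.05001), upper-quartile normalization (0.0502), no low-count filter (0.0513) or a replicate block (0.0534).

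Erythroid markers rose in 7 of 9 members, and in 9 when adjusted over the list alone. Their median was 2.25 (adjusted p = 1.42e-08, and adjusted p = 0.297 with an estimated correlation). The mean log2 CPM was 2.17, 3.16 and 2.42 in control pools and 4.87, 4.84 and 4.17 in STZ pools. Hbb-bs rose from 2.66 to 17.6 CPM and the heme synthesis gene Alas2 from 7.19 to 32.6 CPM. Globin genes have near-identical copies, and Hbb-b2 and Hbb-bt were listed with identical values, so their separate levels are uncertain and they count as 2 of the 7. Hbb-bs and Hbb-b1 overlapped on chromosome 7 with nearly equal counts (25, 23 and 7 against 24, 22 and 6 in control pools), and also count as 2 of the 7. Hbb-b2 and Hbb-bt each lost the call without control pool 1 (adjusted p = 0.0677), control pool 3 (0.134), STZ pool 1 (0.135) or STZ pool 2 (0.1003). Bpgm (0.65 ± 0.17) lost its call without the same libraries (adjusted p of 0.0598 to 0.156) and by limma-voom (0.0533), and Alas2 with a replicate block (0.118). Proximal tubule markers (median -0.08, adjusted p = 0.999) had 1 of 10 called higher, also when adjusted over the list alone. Its test reversed in direction without control pool 1 (median -0.0134), control pool 2 (-0.0724) or STZ pool 2 (0.0207). The called marker was Cyp4b1 (0.40 ± 0.12), which lost its call without every library but control pool 1 (adjusted p of 0.0814 to 0.149). Cyp4b1 also lost it with a replicate block (adjusted p = 0.0576), upper-quartile normalization (0.0535) or a fit that was not robust (0.0581). Leukocyte markers (median 0.31, adjusted p = 0.471) had 1 of 14 called higher and 2 lower, and 2 and 2 when adjusted over the list alone, with the B cell gene Cd79a lower (-1.71 ± 0.31). The leukocyte median was 0.0406 without control pool 3 and 0.483 without control pool 2. Fcer1g, the member called higher (0.98 ± 0.24), lost its call without control pool 1 (adjusted p = 0.117), STZ pool 1 (0.0738) or STZ pool 2 (0.0552).

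**Figure D4:**
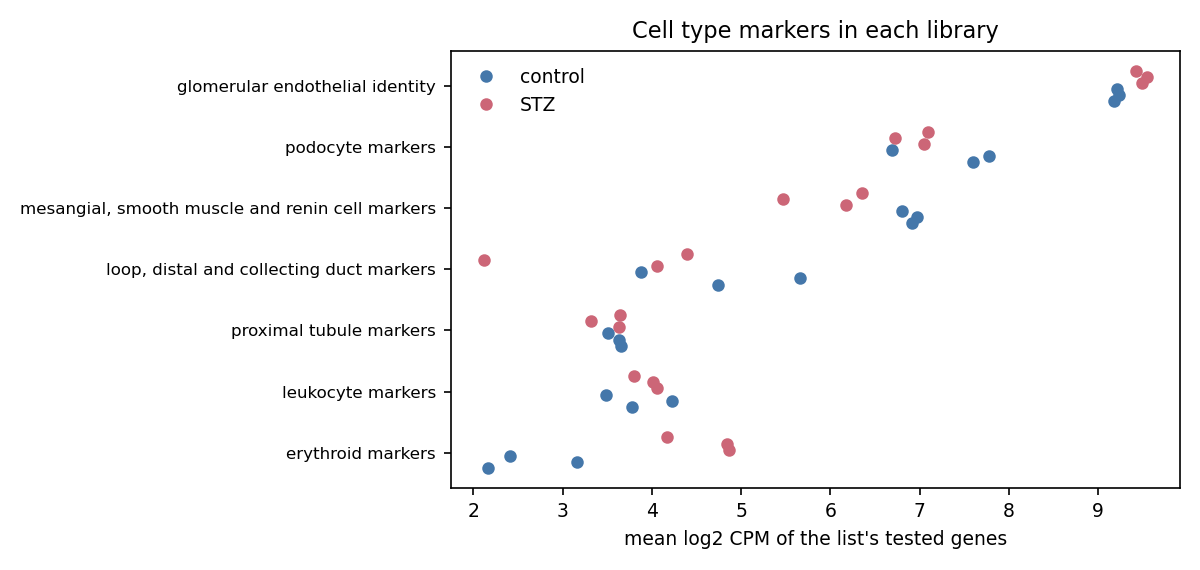
Mean log2 CPM (horizontal axis) of the marker lists of endothelial and other cell types in each of the 6 libraries, 1 point per library, control in blue and STZ in red. Mesangial and mural markers were lower in each STZ pool (5.47 to 6.36) than in each control pool (6.80 to 6.97), and endothelial identity genes higher (9.43 to 9.54 against 9.18 to 9.23).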

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

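Thinning, removal of GC and length trends, leaving out genes with a blank cell, with more than 1 listed transcript or on X and Y, and the marker covariates were chosen only after the results were seen. With all 6 libraries, the count of 1251 called genes stayed between 1177 and 1471 under other normalizations, filters and tools. DESeq2 called 1285 (1141 shared) and upper-quartile normalization 1246, and 1842 passed a threshold of 0.10 (866 lower). A log2 fold change of at least 1 left 190 (98 higher, 92 lower) by its own construction. Leaving out 1 library at a time gave 662 to 1291 genes, 426 to 695 higher and 236 to 596 lower, with 12 to 15 called lists against 16. Smaller groups lower the power, but why STZ pool 1 and control pool 1 mattered most was not tested. With a replicate block there were 1001 genes, 940 of them shared, and 15 lists. Thinning to the shallowest library gave 1073 genes (982 shared) and 14 lists, without leukocyte adhesion (adjusted p = 0.101) and oxidative stress (0.0785). Removal of GC and length trends gave 1497 (1198 shared) and 12 lists, without oxidative phosphorylation (adjusted p = 0.591), oxidative stress (0.0881), glycolysis (0.05005) and leukocyte adhesion (0.0546). Genes with 1 listed transcript gave 826 (463 higher, 363 lower) because 9240 were tested. The podocyte covariate gave 1926 (1075 higher, 851 lower), and the cause was not tested. The mesangial and mural covariate left 200 (137 higher, 63 lower), 152 of them shared and 9 earlier calls turned in sign. That covariate was lower in every STZ pool than in every control pool, so the fit could separate it from the group only weakly. With an estimated correlation 0 lists were called. By fry 10 were called, 8 of them among the 16, while the stress, mesangial and mural, podocyte, loop, oxidative phosphorylation, glycolysis, leukocyte adhesion and oxidative stress lists were not.

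Of 99 called named genes, 74 passed in every setting fixed in advance other than the fold minimum, 75 without each library in turn, 93 with the podocyte covariate and 41 with the mesangial and mural covariate. Of 2765 named-gene values under alternatives 2492 kept direction and side, 233 were weaker, 33 stronger and 7 reversed, all of uncalled genes. Without 1 library Podxl lay between -0.0659 and 0.143 (reversed without control replicate 3). With the podocyte covariate Slc6a6 reversed to -0.0327 and Slc12a3 to 0.942. With the mesangial and mural covariate Cald1 reversed to 0.0521, Mylk to 0.159, Tm4sf1 to 0.0298 and Slc12a3 to 3.53. Of 364 list values, 296 kept direction and side, 50 were weaker, 4 stronger and 14 reversed in the direction of the test, all in uncalled lists. The median of proximal tubule markers was then -0.0826 with DESeq2 size factors, -0.0772 with the replicate block, -0.083 with fry, 0.0379 thinned and -0.0517 without GC and length trends. It ran from -0.168 to 0.0207 without 1 library (reversed without control replicates 1 and 2 and STZ replicate 2). Without 1 library the interferon list ran from -0.0228 to 0.0481 (reversed without control replicates 2 and 3) and the glycocalyx list from -0.199 to -0.0594 (reversed without control replicate 2). The ribosomal list ran from -0.0465 to 0.131 (reversed without control replicate 3 and STZ replicate 1) and reversed at -0.0325 without GC and length trends. The cause of these reversals was not tested. At 4387339 counts in the shallowest library, 59.7% of simulated genes changed 1.5-fold were recovered, so a gene that did not pass is not shown to be unchanged.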

Other observations

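The splits of the libraries were fixed before the data were examined, but their bound was written afterwards. The term enrichment and all other tests below were chosen only after the results were seen. For glucocorticoid exposure and time of day, the choice followed the rise of Fkbp5 and Zbtb16. Only their predictions were written before those tests were run. Among annotation terms carried in the files, those of the cell surface and of vessel growth held more of the higher genes than chance gives, but their members as a whole moved little. Among 691 annotated genes higher in STZ, 25 of 2045 terms passed in a hypergeometric test over 12455 annotated genes. Cell surface held 44 of its 279 genes (adjusted p = 5.44e-07), positive regulation of angiogenesis 16 of 65 (adjusted p = 0.00035) and positive regulation of endothelial cell proliferation 12 of 41 (adjusted p = 0.000939). The median log2 fold change of all their members was 0.0232, 0.155 and 0.156, and that of the terms angiogenesis and vasculogenesis was 0.0165 and -0.015. The fixed angiogenesis list was not called (adjusted p = 0.552). Protein folding held 18 of 101 (adjusted p = 0.00283) and FK506 binding, the prolyl isomerase family of Fkbp5 and Fkbp14, 6 of 14 (adjusted p = 0.0119), with medians of 0.11 and 0.141. Among 548 annotated lower genes 1 term passed, intracellular signal transduction, with 29 of 280 (adjusted p = 0.0334).

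The 6 libraries make 10 splits into 3 and 3, too few to give a share under 0.05. For the called genes 1 split, the real one, gave 1251, and the highest of the others gave 10. Every other split had pools of both groups on each side, so the difference between groups widened the spread there. Few calls in those splits therefore do not rule out chance. For the gene lists 1 split, the real one, gave 16, and the highest of the others, control pools 1 and 2 with STZ pool 3 against the rest, gave 14.

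Xist in the control pools and Y-linked genes in the STZ pools form the clearest split of the libraries. A male among the mice of a control pool is argued against by Ddx3y, which reached at most 2.498% of the STZ mean in a control pool. Mean Eif2s3y was low as well (1.13 against 92.8 CPM in STZ). Kdm5d (2.72 against 42.0 CPM) and Uty (3.46 against 33.3 CPM, and 4.66 CPM in control pool 2) were less so. A female among the mice of an STZ pool is argued against too, since Xist was at 0.687 CPM in STZ against 709 CPM in control. Control pools from female and STZ pools from male mice go with all of these values, although the labels give no sex. All 4 X-linked partners of the Y genes, Ddx3x (-0.49), Eif2s3x (-0.61), Kdm5c (-0.53) and Kdm6a (-0.70), were lower in STZ as well. For the autosomal calls, sex rather than STZ as the cause cannot be told apart, because 0 libraries had sex-linked genes that went against their group. An effect of STZ, of sex or of both stays open for every autosomal gene.

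Mesangial and mural markers were on average lower and endothelial identity genes on average higher in the STZ pools, which were sorted on EYFP, a step that should remove mural cells. A higher share of endothelial RNA alone is argued against as the source of all the identity folds. Of the 26 identity genes, 15 had a 95% interval that left out the list median, 7 above it and 8 below. The intervals were counted on both sides here, by a bound written after the calls were known. The count speaks only against the same shift in every gene. A higher share beside changes of separate genes stays open, and fewer mural cells would bring such a share. Fewer mesangial and mural cells in the STZ pools may explain the lower markers and stay open, with 18 of 19 markers negative and 3 with an interval wholly below the median. An earlier form of that test counted the intervals on both sides, 8 of 19, which by its bound of 6 would have counted against a single shift. It was changed after the result was seen, since markers that endothelial cells also make (abundant Cald1 at 287 CPM and Mylk at 341 CPM in STZ) can only lie above, and a change within mural cells stays open too.

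Fkbp5, Zbtb16 and 9 other known glucocorticoid-induced genes that drew attention were all 11 higher, with a median of 0.85. They were picked after their values were seen, so their direction does not test a cause. Higher glucocorticoid exposure in STZ mice may underlie the rise of these glucocorticoid-induced genes. A rise was predicted for 13 such genes not looked at before: their median was -0.0174 and their mean 0.149 with an SE of 0.13 across genes, 4 were called higher and 1 lower. Camera did not pass (p = 0.0934, and p = 0.150 with an estimated correlation), while fry, which does not compare a list with other genes, passed upward (p = 0.0332). The bound set in advance, a median at or below 0, was met, but by less than the SE of 0.13. That SE is of the mean across genes, not of the median or of pools. The condition on the SE was added only after the result was seen. Members went both ways, so the test does not decide. A different time of day at harvest stays open. The medians of clock genes of opposite phase, -0.43 for that of Arntl and 0.48 for that of Dbp, had opposite signs. They differed by -0.91, short of the 1 predicted. The SE of 0.23 given to this difference is that of the means across 4 and 7 genes, not of medians or pools. Of the Arntl phase 1 gene was called lower, Arntl (-0.56), and all 4 were negative. Of the Dbp phase 3 were called higher, Per2 (1.37), Tef (0.52) and Per3 (0.48). Dbp (0.60), Nr1d1 (0.12), Nr1d2 (0.003) and Hlf (-0.34) did not pass. Camera and fry put the Arntl phase lower and the Dbp phase higher at an unadjusted threshold of 0.05. With an estimated correlation camera put neither there. Stronger dissociation stress stays open with 6 of 19 Fos, Jun, Egr, Nr4a, Atf3 and heat shock genes higher. That list replaced, after the result was seen, a first list of 10, because the first list had left out called genes. The first list had 0 called higher and a median of -0.14. By the bound used for the 19 genes it would have counted against such stress, so the outcome depends on the choice of list.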
